A study of Mus musculus with 16 samples.

How the data were processed

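RNA-seq of sorted mouse CD8+ T cells was read from a deposited matrix of raw counts, with 34573 gene symbols and 12 libraries, 3 for each of Tn, Teff1, Teff2 and Tex. These deposited counts are whole numbers per gene, of which 11535 genes had no count in any library. A second deposited matrix holds normalized values of the authors on a log2 scale for 21574 genes, exactly those with at least 2 counts over the 12 libraries. Its values run from -1.99 to 17.7 and its transformation is not stated, so it served as an alternative only. The submitters' processing notes name the mouse assembly mm10 and the tools BWA, Juicer, HISAT2, HTSeq and DESeq2, without versions or settings. All columns were mapped to a library by group and replicate number. The 4 Hi-C samples have no processed file and were not analysed here.

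Symbols were matched to a mouse annotation of assembly mm10 (GRCm38.p6), which gave the coordinates. Of the symbols 25335 matched a current symbol and 2404 matched 1 older symbol, together 80.2%. The counting is not stated to be stranded, so antisense transcripts and overlapping genes cannot be told apart. Counts of close copies, such as the Gzmc family, Serpinb9b and Serpinb9, Tgtp1 and Tgtp2, and the pseudogenes of Rps2 and Rpl3, are uncertain for the same lack of settings. List members that the file holds under an older name (Vsir, Msmo1, Wapl, Kmt2a and Adgre1) were read under that name, and Kmt2d, Trdc, Tcrg-C4, Ighd, Hbb-bs and Hbb-bt were not found.

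Library totals were 14.7 to 21.2 M counts, with 17262 to 18605 genes detected on average by group and 1.44% to 1.92% of counts in mitochondrial mRNA. Where all libraries of a group had 0 counts, a fold is a bound against a floor of 3 counts per library. With 1 to 3 counts in a group, the ratio is given with its 95% counting interval. Both cover counting error only. CPM were computed with TMM-scaled library sizes, but the marker sums below with the plain library totals.

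Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and edgeR's filter by expression (14332 genes kept), on all 12 libraries with group as the term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and counts are also given at a log2 fold change of at least 1 in size. The comparisons were Teff1 with Tn, Teff2 with Teff1, Tex with Teff2, Teff2 with Tn and Tex with Tn. Comparisons that share a group are not independent. The tests, the 23 gene lists, the 12 marker lists, the alternatives listed first below and the rule for naming genes were chosen before the data were examined.

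Whether replicate numbers pair the libraries was checked by correlating, across genes, deviations from the group mean. For Tex and Teff2 r was 0.81, 0.72 and 0.67 for equal numbers and at most 0.09 otherwise, so these libraries were treated as 3 pairs, and a fit within pairs on the 6 day 5 libraries (13096 genes) was added after the data were examined. Its common dispersion was 0.00941, against 0.0994 over all libraries. For the other comparisons r for equal numbers was 0.15, 0.17 and 0.00 (Teff1 and Tn), 0.50, 0.25 and 0.04 (Teff2 and Teff1, where an unequal pair reached 0.45), 0.01, 0.10 and 0.08 (Teff2 and Tn) and 0.09, 0.16 and 0.02 (Tex and Tn), and they were not paired.

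The 23 lists were those of naive and memory, activation, cytotoxic effector, inhibitory receptor, exhaustion-associated transcription factor, secreted cytokine and chemokine, chemokine receptor and adhesion, G2 and M phase, S phase, glycolysis, respiratory chain, cholesterol synthesis, ribosome biogenesis, cytosolic ribosomal protein, amino acid uptake and one-carbon, integrated stress response, interferon-stimulated, IL-2 and STAT5 response, hypoxia-inducible, p53 target, chromatin architecture, chromatin-modifying and histone chaperone and variant genes. They were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the 23 lists of a comparison. Camera with an estimated correlation and fry were alternatives. Members were also counted when adjusted over the list alone. Markers of CD8 T, CD4 and regulatory T, gamma delta T, NK and B cells, antigen-presenting cells, macrophages and monocytes, dendritic cells, neutrophils, erythroid cells, platelets and stromal and endothelial cells were summed in CPM. Il2ra, Batf3 and Cd5 are in a marker list and also in the activation list, and Gzma is also in the cytotoxic list. Deviations of replicate 1 used log2 CPM with 0.5 CPM added.

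The rule for naming genes took, per comparison, the 6 largest rises and 6 largest falls among called genes with at least 10 CPM in the higher group and no overlap between libraries, leaving out predicted genes, pseudogenes and antigen receptor segments. It also took up to 3 called members of each list in the direction of most called members and up to 1 in the other, with at least 2 CPM in the higher group, the genes of the sorted proteins, and the most abundant marker of each other cell type. Within pairs, the same direction in all 3 pairs replaced the lack of overlap. Of the genes under the rule, 2 are not reported here, and not every other one is printed. Tox within pairs, Gzmb and Ifng between Teff2 and Teff1, and the genes named for Teff2 and Tex against Tn fall outside it and were chosen after their values were seen.

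The alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter on low counts (23038 genes), a filter at 2 CPM (12441 genes), the 6 compared libraries alone, a replicate block, and leaving out each library. Upper-quartile factors moved the median log2 fold change of all genes by -0.14, -0.11 and -0.12 for Teff1, Teff2 and Tex against Tn. Added after the data were examined were limma on the authors' log2 values, leaving out Tn replicates 1 and 3, leaving out replicate 1 of the activated states, and the replicate block on the 6 compared libraries. Where 1 library of a group is left, it is assumed to vary like the other groups.

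The fits were tested on simulated data in which 200 genes were changed by 1.5, 2 or 4 fold between libraries of the same structure. The share recovered was 1.61%, 21.4% and 63.2% in the layout of Teff1 and Tn (6 false of 65 calls), 0%, 20.0% and 67.5% for Teff2 and Teff1 (2 of 67), 0%, 15.9% and 59.2% for Tex and Teff2 (2 of 57), 4.48%, 13.1% and 63.9% for Teff2 and Tn (4 of 61), 0%, 9.21% and 54.7% for Tex and Tn (1 of 37), and 64.5%, 84.6% and 91.8% within pairs (15 of 177). Only 200 genes were changed, while 7012 were called between Teff1 and Tn, and the adjustment is more lenient where more genes change. These shares therefore do not give the sensitivity of the comparisons with Tn. The simulation within pairs took its spread from the paired fit itself (common dispersion 0.00941), so its shares hold only if that low spread is right. With the spread of all 12 libraries the paired fit of the real data called 3 genes. Camera called the changed list and 0 of 20 unchanged lists. The simulated genes varied independently, whereas the G2 and M phase list had an estimated correlation of 0.94 for Teff1 and Tn. The simulation therefore does not test the preset correlation. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.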

Results

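RNA-seq was collected from mouse CD8+ T cells in 4 states of activation in culture, to follow how gene expression changes through this process. Naive CD8+ T cells were isolated from the spleens of C57BL/6 mice and stimulated with antibodies against CD3e and CD28 (10 µg/ml each), which engage the T cell receptor complex and a co-stimulatory receptor. IL-2, a T cell growth factor, was added at 300 U/ml after the first night. Tn cells were sorted at day 0 as CD8+ cells by surface markers of naive cells, among them a lack of CD44. Teff1 cells were sorted at day 2 and Teff2 cells at day 5, both as PD-1+ TIM-3- cells, and Tex cells were sorted at day 5 as PD-1+ TIM-3+ cells. PD-1 and TIM-3 are receptors that restrain T cell responses. Each state had 3 libraries, each made from 0.2 M cells. The libraries held 14.7 to 21.2 M counts. The means were 15.7 ± 1.66 M in Tn, 19.7 ± 2.10 M in Teff1, 17.9 ± 1.51 M in Teff2 and 19.0 ± 0.924 M in Tex (SD, n = 3 each). A count of 0 in 1 library therefore allowed up to 0.142 to 0.205 counts per M counts (CPM), the level of 3 counts. No label says that replicates came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. The series also holds 4 Hi-C samples, which were not analysed here.

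Within each state the libraries correlated with r between 0.949 and 0.985 across genes on the log2 CPM scale, and no pair of libraries was identical. The first principal component held 65.8% of the variance and separated Tn from the 3 activated states, the second held 11.2% and the third 7.84%. Replicate 1 of the activated states stood apart from replicates 2 and 3. Against their mean on the log2 scale, the median of the cholesterol synthesis list in replicate 1 was -1.94 in Teff1, -1.62 in Teff2 and -1.39 in Tex. The median of the G2 and M phase list was -0.36, -2.38 and -1.87 in the same order, that of the interferon-stimulated list -0.92, -0.75 and -1.13, and that of the p53 target list 0.41, 1.07 and 1.11.

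The transcripts of 4 sorted proteins were read first, because they check the labels. Havcr2, which encodes TIM-3 (chromosome 11, 46454931 to 46481255), stood at 27.9 ± 14.9 CPM in Tex and at 0.433 ± 0.177 CPM in Teff2, 0.362 ± 0.171 CPM in Teff1 and 1.69 ± 1.12 CPM in Tn (SD, n = 3 each). Pdcd1, which encodes PD-1 (chromosome 1, 94038305 to 94052553), stood at 4.48 ± 2.14 CPM in Tn and at 90.7 ± 17.2, 167 ± 59.4 and 192 ± 43.0 CPM in Teff1, Teff2 and Tex. Cd44 had 25 ± 16.3 CPM in Tn, 87.9 ± 16.4 in Teff1, 246 ± 10.1 in Teff2 and 300 ± 147 in Tex. Cd8a had 1199 ± 309 CPM in Tn and between 770 and 815 CPM on average in the activated states.

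**Figure D1:**
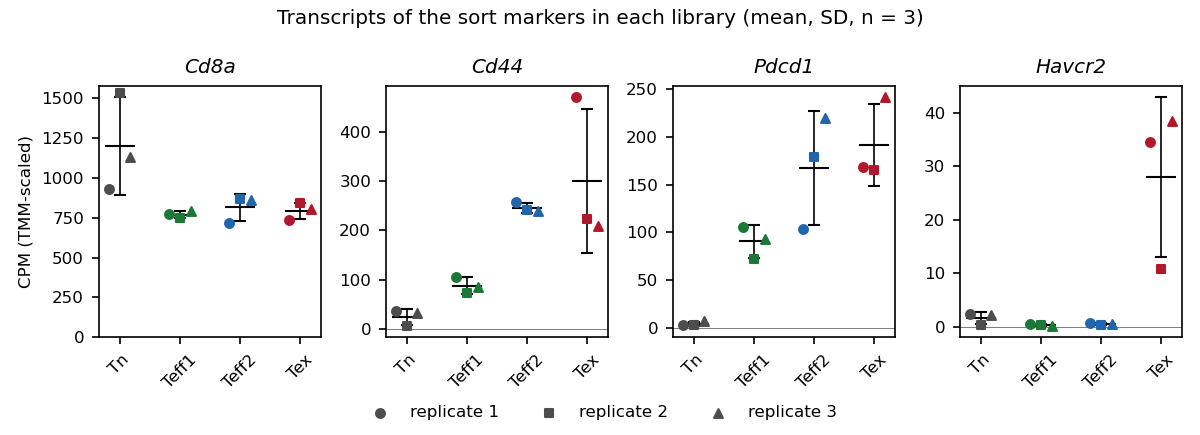
Transcript levels (CPM, TMM-scaled, linear axes) of 4 genes that encode sorted proteins, with 1 symbol per library and the mean ± SD of the 3 libraries of each state. Havcr2 lay between 10.9 and 38.4 CPM in the 3 Tex libraries and between 0.182 and 2.45 CPM in the other 9, and Pdcd1 was lower in the 3 Tn libraries than in any activated library.

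Markers of other spleen cells were measured in the same libraries. The summed B cell markers had 1507, 641 and 2480 CPM in Tn replicates 1, 2 and 3. The MHC class II genes of antigen-presenting cells had 1493, 166 and 2348 CPM, the NK cell markers 174, 14.4 and 328 CPM, and the macrophage and monocyte markers 322, 85.4 and 228 CPM. All 4 sums were lowest in Tn replicate 2. In the activated states the mean sums were 241, 185 and 139 CPM for B cells in Teff1, Teff2 and Tex. They were 69.9, 107 and 87.0 CPM for MHC class II, 4.89, 16.2 and 24.6 CPM for NK cells and 10.9, 12.2 and 9.47 CPM for macrophages in the same order. Erythroid markers had 96.9 ± 38 CPM in Tn, platelet markers 32.7 ± 22.0, neutrophil markers 6.39 ± 3.23, stromal and endothelial markers 176 ± 13.5 and gamma delta T cell markers 13.2 ± 5.91. In Teff1 these sums were 2.54 ± 1.02, 3.11 ± 2.07, 0.253 ± 0.0769, 63.1 ± 11.5 and 7.0 ± 8.99 CPM. The dendritic cell sum had 31.7 ± 21.7 CPM in Tn and 36.4 ± 16.1 in Teff1, and the CD4 and regulatory T cell sum 82.5 ± 48.1 and 855 ± 111 CPM. Batf3 and Il2ra lead these last sums in the activated states but not in Tn, and are also members of the T cell activation list. Without Batf3 the dendritic cell sum had 30.4 CPM in Tn and 3.24, 11.5 and 12.1 CPM in Teff1, Teff2 and Tex. Without Il2ra the CD4 and regulatory T cell sum had 78.9 CPM in Tn and 31.2, 88.0 and 99.6 CPM. Markers of CD8 T cells had 4579, 6388 and 5303 CPM in the Tn libraries and 3717 ± 131, 3922 ± 73.9 and 3753 ± 57.9 CPM in Teff1, Teff2 and Tex.

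**Figure D2:**
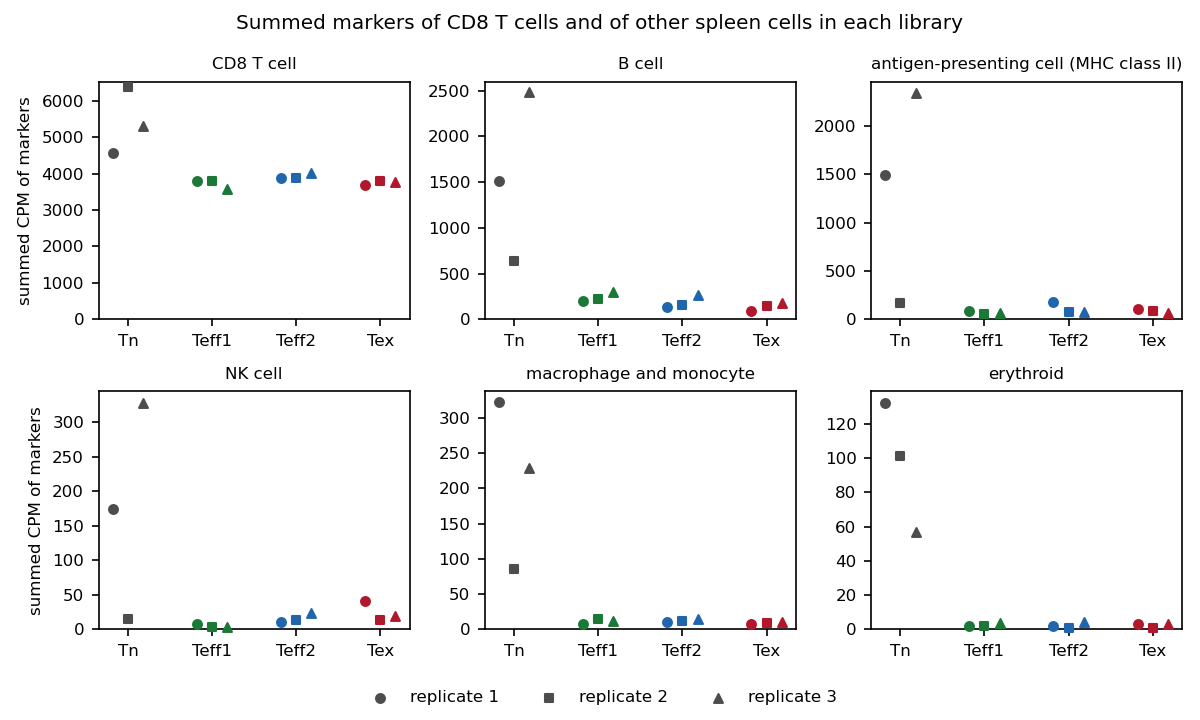
Summed CPM (linear axes) of the markers of CD8 T cells and of 5 other cell types in each library, with 1 symbol per library. The sums of B cells, MHC class II genes, NK cells and macrophages were lowest in replicate 2 among the Tn libraries, and those of B cells, macrophages and erythroid cells were lower in every activated library than in any Tn library.

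The comparison of Teff1 with Tn asked what the first 2 days of stimulation changed. By day 2, genes of DNA replication and cell division had risen throughout. Most genes of amino acid supply and of the integrated stress response had also risen, while most genes typical of naive T cells had fallen. Il2ra, which encodes the high-affinity IL-2 receptor chain (chromosome 2, 11642792 to 11693194), rose from 3.47 ± 2.23 CPM in Tn to 835 ± 134 CPM in Teff1. Gzmb, a granule protease of cytotoxic cells (chromosome 14, 56258836 to 56262334), rose from 14.9 ± 11.9 to 3365 ± 1746 CPM. Klf2, a transcription factor of resting T cells (chromosome 8, 72319062 to 72321654), fell from 749 ± 143 to 11.1 ± 1.73 CPM, and its target S1pr1, the receptor that guides T cells out of lymphoid tissue (chromosome 3, 115710433 to 115715055), fell from 518 ± 56.1 to 9.0 ± 6.45 CPM (SD, n = 3 each). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these changes on the log2 scale were 7.90 (SE 0.51, adjusted p = 2.66e-06), 7.81 (SE 1.07, adjusted p = 1.66e-04), -6.08 (SE 0.59, adjusted p = 1.90e-05) and -5.84 (SE 0.53, adjusted p = 1.37e-05), each in all 3 libraries.

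Among genes with the largest rises, Lif, a cytokine of the IL-6 family, went from 0.308 ± 0.164 to 175 ± 87.2 CPM, and Chac1, which degrades glutathione, from 0.0985 ± 0.0543 to 22.7 ± 10.7 CPM. Cth, the enzyme that makes cysteine from cystathionine, had no count in Tn and 69.6 ± 57.6 CPM in Teff1, at least 361-fold higher against a floor of 3 counts per library. Lipg, an endothelial-type lipase, had 2 counts in Tn and was 413-fold higher in Teff1 (95% interval 114 to 3414), but its call ended without Tn replicates 1 and 3. Among the largest falls, Slc40a1, the cellular iron exporter, had 24.7 ± 9.96 CPM in Tn and no count in Teff1, at least 161-fold lower. The next 5 had 1 count in Teff1 each. Vcam1, an adhesion molecule, was 1547-fold lower (95% interval 277 to 61140) and Grm6, a glutamate receptor, 979-fold lower (175 to 38700). Cd180, a receptor of B cells and myeloid cells, was 962-fold lower (172 to 38050), Marco, a macrophage scavenger receptor, 839-fold lower (150 to 33180), and C1qb, a complement chain made by macrophages, 758-fold lower (136 to 30000). These intervals cover counting error only. In Tn replicates 1, 2 and 3, Marco had 39.6, 2.59 and 1.67 CPM, Cd180 18.1, 1.5 and 25.2 CPM, and Grm6 16.2, 17.1 and 15.1 CPM, beside the uneven markers of other spleen cells in these libraries. For the genes named here among the largest falls, a fall within CD8+ T cells cannot be told apart from a loss of other spleen cells.

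Of the naive and memory T cell list, 17 of 22 members fell and 1 rose. Besides Klf2 and S1pr1, the transcription factor Klf3 fell from 247 ± 41.2 to 13.1 ± 3.82 CPM, and the survival gene Bcl2 rose from 201 ± 35.1 to 416 ± 155 CPM. The list as a whole was lower by camera, a test of a list against all other genes (adjusted p = 3.20e-07; adjusted p = 0.0981 with an estimated correlation). Of the chemokine receptor and adhesion list, 16 of 28 fell and 4 rose (camera adjusted p = 0.0102; adjusted p = 0.342 with an estimated correlation). Ccr9, a receptor for homing to the gut, fell from 158 ± 49.9 to 1.96 ± 1.79 CPM, and Ccr4, a skin homing receptor, rose from 1.53 ± 0.547 to 19.9 ± 3.30 CPM. Of the T cell activation list, 17 of 23 rose and none fell (camera adjusted p = 3.20e-07; adjusted p = 0.147 with an estimated correlation). With upper-quartile scaling 1 member of the activation list fell. The co-stimulatory receptor Tnfrsf9 rose from 12.4 ± 0.769 to 513 ± 65.0 CPM and the transcription factor Batf3 from 1.31 ± 1.04 to 33.6 ± 18.2 CPM. Of the IL-2 and STAT5 response list, 14 of 18 rose and Socs3, a feedback inhibitor of cytokine signalling, fell from 149 ± 12.6 to 41.6 ± 16.2 CPM, while its relative Socs2 rose from 1.54 ± 1.09 to 64.7 ± 28.9 CPM (camera adjusted p = 5.18e-07; adjusted p = 0.0981 with an estimated correlation). Of the secreted cytokine and chemokine list, 16 of 22 rose and 2 fell (camera adjusted p = 5.11e-04; adjusted p = 0.322 with an estimated correlation). The chemokine Xcl1 rose from 7.34 ± 4.50 to 310 ± 164 CPM and Spp1, the secreted phosphoprotein osteopontin, from 0.186 ± 0.200 to 29.1 ± 18.6 CPM, while the chemokine Ccl5 fell from 59.9 ± 46.4 to 4.46 ± 1.08 CPM. The median log2 fold changes of the naive, receptor, activation, IL-2 and cytokine lists were -1.8, -1.6, 2.1, 1.8 and 3.0. In the fit without Tn replicates 1 and 3 they were -2.0, -0.7, 2.7, 2.1 and 4.2. Without Tn replicates 1 and 3, the libraries with the higher sums of other-cell markers, 15 of the 17 falls of naive genes and 10 of the 16 falls of receptors remained called. So did 15 of the 17 rises of activation genes, 13 of the 14 rises of IL-2 genes and 11 of the 16 rises of cytokines. The calls of Bcl2 and Ccl5 ended.

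All 29 members of the S phase list rose (camera adjusted p = 4.17e-17; adjusted p = 0.246 with an estimated correlation), as did all 26 of the G2 and M phase list (camera adjusted p = 8.82e-10; adjusted p = 0.388 with an estimated correlation). Dtl, which controls the licensing of replication origins, rose from 3.45 ± 1.74 to 148 ± 27.0 CPM and Aurkb, a mitotic kinase, from 3.13 ± 1.67 to 153 ± 25.1 CPM. Of the histone chaperone and variant list, 12 of 16 rose and none fell, among them Chaf1a, a subunit of chromatin assembly factor 1, from 5.57 ± 2.95 to 122 ± 8.64 CPM (camera adjusted p = 5.47e-06; adjusted p = 0.334 with an estimated correlation). Of the chromatin architecture list, 13 of 27 rose and 4 fell (camera adjusted p = 5.23e-03; adjusted p = 0.517 with an estimated correlation). Ncapg and Ncaph, subunits of the condensin complex, rose from 2.92 ± 1.54 to 115 ± 4.85 CPM and from 5.82 ± 1.20 to 113 ± 11.2 CPM, while Lmna, which encodes lamins A and C, fell from 6.16 ± 4.89 to 0.901 ± 0.219 CPM. Of the chromatin-modifying enzymes, 11 of 28 rose and 7 fell and the list was not called. Ezh2, the histone methyltransferase of Polycomb repressive complexes, rose from 27.0 ± 3.50 to 271 ± 5.72 CPM and Tet1, which oxidises methylcytosine, fell from 41.9 ± 4.27 to 8.13 ± 2.62 CPM. After leaving out Tn replicates 1 and 3, 27 of the 29 rises of S phase genes, 25 of the 26 of G2 and M genes, 9 of the 12 of histone genes, 8 of the 13 of architecture genes and 3 of the 11 of modifying enzymes remained called. So did 1 of the 4 falls of architecture genes and 3 of the 7 falls of modifying enzymes.

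Of the amino acid uptake and one-carbon list, 17 of 18 rose, among them Psat1, an enzyme of serine synthesis, from 24.5 ± 1.37 to 529 ± 65.7 CPM (camera adjusted p = 8.82e-10; adjusted p = 0.0981 with an estimated correlation). Of the integrated stress response list, 18 of 20 rose, among them Asns, asparagine synthetase, from 0.948 ± 0.693 to 176 ± 80.6 CPM (camera adjusted p = 8.45e-07; adjusted p = 0.246 with an estimated correlation). In replicate 1 of Teff1 the median deviation of this list was 0.92 on the log2 scale. Of the ribosome biogenesis list, 25 of 26 rose, among them Ncl, the nucleolar protein nucleolin, from 622 ± 76.7 to 2548 ± 866 CPM (camera adjusted p = 2.78e-10; adjusted p = 0.334 with an estimated correlation). Of the glycolysis list, 15 of 20 rose, among them Hk2, which starts glycolysis, from 5.80 ± 2.85 to 156 ± 44.7 CPM, and Slc16a3, a lactate exporter, from 3.84 ± 0.908 to 136 ± 44.8 CPM (camera adjusted p = 3.34e-06; adjusted p = 0.405 with an estimated correlation). Of the respiratory chain list, 22 of 28 rose, among them Cycs, cytochrome c, from 43.3 ± 6.29 to 174 ± 61.8 CPM (camera adjusted p = 3.20e-07; adjusted p = 0.405 with an estimated correlation). Of the cholesterol synthesis list, 14 of 24 rose, among them Cyp51 from 17.3 ± 3.12 to 245 ± 159 CPM (camera adjusted p = 9.51e-04; adjusted p = 0.599 with an estimated correlation). Of the hypoxia-inducible list, 10 of 19 rose and 2 fell, and Vegfa, an angiogenic growth factor, rose from 2.35 ± 1.92 to 84.5 ± 37.2 CPM (camera adjusted p = 0.0160; adjusted p = 0.517 with an estimated correlation). No member of the first 6 of these lists fell with TMM scaling, while 1 glycolysis gene fell with upper-quartile scaling. Of the cytosolic ribosomal proteins, 5 of 30 rose and none fell with TMM scaling, while 1 rose and 2 fell with upper-quartile scaling, and the list was not called. When Tn replicates 1 and 3 were left out, 14 of the 17 rises of amino acid genes, 12 of the 18 of stress response genes, 8 of the 25 of ribosome biogenesis genes and 5 of the 15 of glycolysis genes remained called. So did 2 of the 22 of respiratory genes, 1 of the 14 of cholesterol genes (Cyp51 not among them), 3 of the 10 of hypoxia genes and 0 of the 5 of ribosomal proteins. In that fit, with 1 Tn library, the median log2 fold changes were 1.08 for ribosome biogenesis, 1.81 for glycolysis, 0.83 for the respiratory chain, 1.87 for cholesterol synthesis and 0.70 for hypoxia. With all Tn libraries they were 1.21, 1.98, 0.84, 1.98 and 1.0. Camera still called these 5 lists higher there (adjusted p = 1.13e-09, 5.36e-06, 3.24e-06, 2.53e-03 and 0.0269; adjusted p = 0.355, 0.414, 0.455, 0.560 and 0.532 with an estimated correlation).

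Lists of effector and exhaustion genes moved in both directions and were not called by camera. Fry called the exhaustion-associated transcription factors higher (adjusted p = 0.00662), while camera did not (adjusted p = 0.220; adjusted p = 0.460 with an estimated correlation). With Tn replicates 1 and 3 left out camera called this list higher (adjusted p = 0.0269; adjusted p = 0.282 with an estimated correlation). Of the cytotoxic effector list, 7 of 21 rose and 6 fell. Ifng, the cytokine interferon gamma, rose from 5.93 ± 5.73 to 202 ± 99.0 CPM and Tbx21, a transcription factor of effector cells, from 16.5 ± 12.2 to 90.4 ± 13.0 CPM, while Klrg1, a receptor of differentiated effector and NK cells, had 1 count in Teff1 and was 236-fold lower (95% interval 41.8 to 9352). Of the inhibitory receptor list, 7 of 19 rose and 9 fell. Lag3 rose from 3.40 ± 1.60 to 207 ± 40.4 CPM, and Cd244, a receptor also found on NK cells, was 582-fold lower with 1 count in Teff1 (95% interval 104 to 23030). Of the exhaustion-associated transcription factors, 7 of 15 rose and 4 fell. Nr4a3, induced by T cell receptor signals, rose from 23.7 ± 13.3 to 588 ± 151 CPM and Irf4 from 40.0 ± 38.9 to 575 ± 37.5 CPM, while Maf fell from 10.2 ± 7.31 to 0.633 ± 0.759 CPM. The falls stood beside the NK cell sums of 174, 14.4 and 328 CPM in the Tn libraries. The median log2 fold changes of the cytotoxic, inhibitory receptor and exhaustion factor lists were 0.44, -0.80 and 0.37. In the fit without Tn replicates 1 and 3 they were 0.30, -0.16 and 0.29. Lost calls in that fit do not separate a smaller fold from the lower power of 1 Tn library. Without Tn replicates 1 and 3, 5 of the 7 rises and 1 of the 6 falls of cytotoxic genes remained called. So did 6 of the 7 rises and 3 of the 9 falls of inhibitory receptors, and 7 of the 7 rises and 1 of the 4 falls of exhaustion factors. The calls of Klrg1 and Maf ended. Of the interferon-stimulated list, 3 of 29 rose and 8 fell. Oas2, an antiviral enzyme, fell from 33.1 ± 8.25 to 2.26 ± 0.732 CPM and Gbp2, a guanylate-binding protein, rose from 74.5 ± 15.2 to 534 ± 290 CPM, the latter not called without Tn replicates 1 and 3. Of the p53 target list, 6 of 18 rose and 3 fell. Cdkn1a, a cell cycle inhibitor, rose from 2.91 ± 3.32 to 64.8 ± 61.0 CPM and Sesn1, an inhibitor of growth signalling, fell from 133 ± 3.62 to 32.9 ± 3.59 CPM. With Tn replicates 1 and 3 left out, 0 of the 3 rises and 5 of the 8 falls of interferon-stimulated genes and 3 of the 6 rises and 2 of the 3 falls of p53 targets remained called. In replicate 1 of Teff1 the median deviation of the interferon-stimulated list was -0.92 and that of the p53 list 0.41 on the log2 scale.

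**Figure D3:**
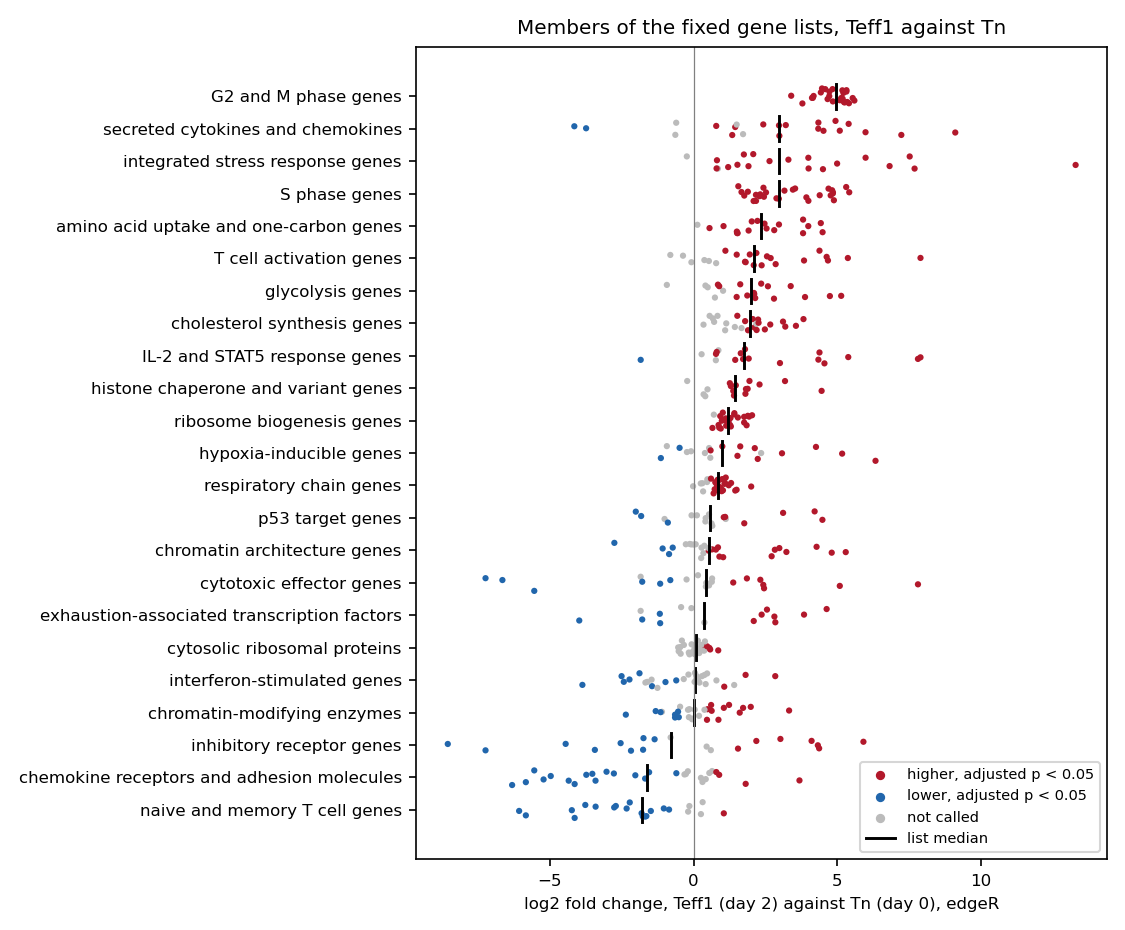
Log2 fold changes of Teff1 against Tn (edgeR) for the members of the 23 fixed gene lists, 1 point per gene, red where higher and blue where lower at an adjusted p under 0.05, grey where not called, with a black bar at each list's median. All 26 G2 and M phase genes lay to the right of 0, and the point farthest right is Cth, whose fitted value depends on the prior count because Tn had no count; with Cth at its bound of 8.50 the median of its list stayed at 2.97.

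In all, 7012 of 14332 genes tested changed between Teff1 and Tn, 3507 higher and 3505 lower, of which 2285 and 2472 had a log2 fold change of at least 1 in size (edgeR). With upper-quartile factors 3017 were higher and 4109 lower. The 3 libraries of the groups did not overlap for 8805 genes (61.4%), where chance gives 10%. Adjusted over the list alone, the counts of rises and falls were 7 and 10 for the inhibitory receptors, 24 and 0 for the respiratory chain, 15 and 0 for cholesterol synthesis, 1 and 0 for ribosomal proteins. They were 19 and 0 for the stress response, 16 and 1 for the IL-2 list and 11 and 2 for the hypoxia list. For the other 16 lists they equalled those over all genes tested. Camera called 16 of the 23 lists with a preset correlation and none with an estimated one, where 4 lists had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move one way on balance, called 16. It did not call the cholesterol synthesis list (fry adjusted p = 0.114), which camera called, and it called the exhaustion-associated transcription factors, which camera did not. For 3 lists that were not called (inhibitory receptors, interferon-stimulated genes, chromatin-modifying enzymes) the median, the mean and the direction of the test differed in sign. Without Tn replicates 1 and 3 the count of changed genes was 3015, with 1435 of the 3507 rises and 1473 of the 3505 falls still called and 26 genes changed in sign. That fit has 1 Tn library, whose spread is taken from the other groups. The expression of the most abundant marker of each other cell type is subject to the same limit. Lyz2 of macrophages fell from 57.6 ± 46.9 to 0.137 ± 0.198 CPM and stayed called. The falls of Cd74 (460 ± 388 to 30.9 ± 6.94 CPM), Ighm (749 ± 228 to 235 ± 55.1 CPM) and Gzma (67.2 ± 63.3 to 0.653 ± 0.612 CPM) were no longer called.

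The comparison of Teff2 with Teff1 asked what changed between day 2 and day 5 in cells of the same PD-1+ TIM-3- sort. Upp1, uridine phosphorylase (chromosome 11, 9118008 to 9136170), rose from 0.128 ± 0.102 to 32.0 ± 14 CPM, and Igfbp2, a binding protein of insulin-like growth factors (chromosome 1, 72824480 to 72852474), from 0.0765 ± 0.0943 to 10.3 ± 4.90 CPM. Myo10, an unconventional myosin (chromosome 15, 25622550 to 25813673), rose from 9.41 ± 1.13 to 120 ± 12.3 CPM and Rgs8, a regulator of G protein signalling, from 2.08 ± 0.275 to 29.2 ± 8.96 CPM. Il6ra, the IL-6 receptor (chromosome 3, 89869324 to 89913196), fell from 20.4 ± 2.44 to 5.66 ± 1.28 CPM, and the pseudokinase Trib2 from 53.6 ± 17.2 to 11.4 ± 1.72 CPM (SD, n = 3 each). On the log2 scale these changes were 7.97 (SE 0.65), 7.08 (SE 0.87), 3.67 (SE 0.25), 3.81 (SE 0.42), -1.85 (SE 0.19) and -2.24 (SE 0.28), with adjusted p between 7.14e-05 and 4.22e-03 (edgeR, Benjamini-Hochberg), in all 3 libraries. These 6 genes kept their call under all 16 alternatives tried. The other genes named by the rule did not. Serpine2, a protease inhibitor, had 11.8 ± 4.31 CPM in Teff1 and 159 ± 102 CPM in Teff2, and Ttc39c 1.16 ± 1.05 and 39.1 ± 26.7 CPM. The ubiquitin ligase Rnf144a had 12.2 ± 4.25 and 2.44 ± 0.414 CPM, the kinase Sgk3 16.2 ± 5.02 and 6.49 ± 1.09 CPM, Nsg2 34.2 ± 1.17 and 13.8 ± 1.23 CPM and Sidt1 49.8 ± 9.48 and 26.0 ± 0.424 CPM. The calls of these 6 ended in 3 to 9 of the alternatives.

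Few members of the fixed lists were called between Teff2 and Teff1. Il6ra and Nsg2 fell among the 22 naive and memory genes. Itgav, an integrin subunit, rose from 66.8 ± 16.5 to 153 ± 21.0 CPM among the 28 receptors and adhesion molecules. Ifit3, an antiviral protein, fell from 4.45 ± 1.26 to 0.954 ± 0.292 CPM among the 29 interferon-stimulated genes. Of the 21 cytotoxic effector genes 0 were called over all genes and 8, all higher, adjusted over the list alone. Gzmb had 3365 ± 1746 CPM in Teff1 and 6005 ± 3649 in Teff2, and Ifng 202 ± 99.0 and 878 ± 848 CPM. Adjusted over the list alone, 6 cytokines and chemokines rose and 1 fell, 1 naive gene rose and 4 fell, 2 p53 targets rose, and 1 S phase gene fell. So did 2 IL-2 genes and 2 receptors or adhesion molecules, with 1 rise in each list. The inhibitory receptor list had 1 rise and 1 fall, the exhaustion factors 1 rise and the interferon-stimulated list 1 fall. The other 13 lists had none. Camera called 3 lists higher (cytotoxic, cytokines, p53 targets) and 8 lower (naive, G2 and M phase, S phase, ribosome biogenesis, amino acid, chromatin architecture, chromatin-modifying, histone). The S phase list had the smallest adjusted p = 1.56e-11. With an estimated correlation none was called (lowest adjusted p = 0.309 with an estimated correlation, for chromatin-modifying enzymes; 2 had an unadjusted p under 0.05). Fry called none, and 4 had an unadjusted p under 0.05. The median deviation of replicate 1 of Teff2 was -2.38 in the G2 and M phase list, -0.86 in the S phase list and 1.07 in the p53 list on the log2 scale. Without replicate 1 of the activated states camera called 7 lists higher and 5 lower. The G2 and M phase list, called lower with it (camera adjusted p = 0.00480; adjusted p = 0.975 with an estimated correlation), was then called higher (camera adjusted p = 0.00451). The chromatin architecture and histone lists were no longer called (camera adjusted p = 0.714 and 0.0950). The median, mean and test of 3 uncalled lists (receptors and adhesion molecules, glycolysis, hypoxia) differed in sign.

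In total 96 of 14332 genes changed between Teff2 and Teff1, 80 higher and 16 lower, 76 and 11 of them by a log2 fold change of at least 1 (edgeR). The groups did not overlap for 2090 genes (14.6%; 10% by chance). DESeq2 called 499 genes. The replicate block gave 313 genes, the replicate block on the 6 libraries compared 277 and those 6 libraries without a block 39. Leaving out Teff2 replicate 3 gave 25 genes, and leaving out Teff1 replicate 1, 2 or 3 gave 41, 26 and 23.

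The comparison of Tex with Teff2 asked how TIM-3+ cells differed from TIM-3- cells of the same day. Havcr2, the gene of the sorted protein, was the gene called in the fit over 4 groups. Its log2 fold change was 5.97 (SE 0.73, edgeR adjusted p = 0.0431). The Tex and Teff2 libraries of 1 replicate number deviated together, so the difference was also fitted within the 3 pairs, a choice made after the data were seen. Within pairs some genes of cytotoxic granules and cytokines were higher in Tex, and some interferon-stimulated and naive-type genes were lower; none of these lists was called by fry or with an estimated correlation. Gzmc, a granzyme (chromosome 14, 56231397 to 56241647), rose from 8.17 ± 6.62 CPM in Teff2 to 71.5 ± 65.6 CPM in Tex, and Serpinb9b, of the family of granzyme inhibitors (chromosome 13, 33027414 to 33040588), from 3.40 ± 2.46 to 37.2 ± 25.2 CPM. Their log2 fold changes were 3.05 (SE 0.12, edgeR adjusted p = 5.03e-06) and 3.46 (SE 0.13, adjusted p = 5.03e-06), higher in 3 of 3 pairs, and that of Havcr2 was 5.98 (SE 0.20, adjusted p = 3.61e-06). Both genes belong to families of close copies, between which the deposited counts may split reads.

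Of the cytotoxic effector list, 9 of 19 rose within pairs, 12 when adjusted over the list alone (camera adjusted p = 3.47e-13; adjusted p = 0.384 with an estimated correlation). Prdm1, the transcription factor Blimp-1 (chromosome 10, 44437174 to 44528558), rose from 1.77 ± 1.65 to 7.55 ± 5.87 CPM and the granzyme Gzma from 0.277 ± 0.281 to 2.58 ± 3.49 CPM. Of the cytokine and chemokine list, 4 of 21 rose, 10 adjusted over the list alone (camera adjusted p = 8.68e-08; adjusted p = 0.371 with an estimated correlation). Ifng (chromosome 10, 118441046 to 118445894) rose from 878 ± 848 to 2165 ± 1427 CPM, the chemokine Ccl9 from 17.3 ± 27.6 to 77.7 ± 123 CPM and Csf2, the growth factor GM-CSF, from 6.13 ± 3.14 to 16.1 ± 10.5 CPM. Of the inhibitory receptors, 3 of 18 rose, Havcr2 among them, and the list was not called. Cd244 rose from 0.364 ± 0.101 to 2.02 ± 1.74 CPM and Entpd1, an enzyme that degrades extracellular ATP, from 3.03 ± 1.92 to 7.36 ± 6.76 CPM. Pdcd1 differed by 0.23 (SE 0.14) on the log2 scale and was not called (adjusted p = 0.422). Of the exhaustion-associated transcription factors, 3 of 14 rose, and the list was not called. Besides Prdm1, Eomes rose from 28.2 ± 6.98 to 50.9 ± 15.5 CPM and Id2 from 32.9 ± 8.19 to 53.4 ± 8.02 CPM. Tox, which the exhaustion list holds, had 18.3 ± 6.42 CPM in Teff2 and 10.9 ± 1.05 CPM in Tex, lower in 3 of 3 pairs, and was not called (adjusted p = 0.0921, edgeR). Adjusted over the list alone, 3 inhibitory receptors rose and 2 fell, and 5 exhaustion factors rose and 3 fell.

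Of the interferon-stimulated list, 5 of 29 fell within pairs and none rose, 14 falling when adjusted over the list alone (camera adjusted p = 3.47e-13; adjusted p = 0.394 with an estimated correlation). Ifi44 (chromosome 3, 151730922 to 151749910) fell from 12.2 ± 10.3 to 5.74 ± 5.23 CPM and Gbp2 from 316 ± 247 to 146 ± 65.4 CPM. Iigp1, an interferon-inducible GTPase (chromosome 18, 60373616 to 60392634), fell from 107 ± 58.8 to 51.9 ± 35.0 CPM, and Ifi203, an interferon-activated gene, from 48.4 ± 12.1 to 23.9 ± 9.75 CPM. Replicate 1 had a median deviation of -0.75 in Teff2 and -1.13 in Tex for this list. Of the naive and memory list, 4 of 22 fell, 8 adjusted over the list alone (camera adjusted p = 2.08e-07; adjusted p = 0.371 with an estimated correlation). Slamf6, a surface receptor (chromosome 1, 171917458 to 171948958), fell from 18.2 ± 9.76 to 7.03 ± 2.53 CPM and Id3, an inhibitor of E protein transcription factors, from 35.8 ± 8.91 to 22.1 ± 8.81 CPM. Further called genes were Lgals3, a galectin, at 46.5 ± 15.3 CPM in Teff2 and 263 ± 238 CPM in Tex, and Adam8, a metalloprotease, at 24.2 ± 24.8 and 83.6 ± 36.7 CPM. Serpina3f fell from 34.3 ± 28.1 to 13.6 ± 12.6 CPM and Sspo from 12.2 ± 19.4 to 3.96 ± 6.32 CPM. In other lists Nupr1, a stress-induced nuclear protein, rose from 12.9 ± 6.58 to 29.5 ± 17.0 CPM and Ccr2, a chemokine receptor, from 1.20 ± 0.720 to 5.05 ± 2.59 CPM. Lmna rose from 3.41 ± 1.46 to 13.3 ± 0.978 CPM and Il2rb, a chain of the IL-2 receptor, from 422 ± 70.1 to 590 ± 79.3 CPM. Of the other cell types, the summed macrophage, B cell and stromal markers were lower in Tex in each of the 3 pairs. The gamma delta T cell markers (4.09 CPM in Teff2 and 8.17 CPM in Tex) were higher in each. So was the dendritic cell sum (58.2 and 93.3 CPM), but without the activation gene Batf3 it had 11.5 and 12.1 CPM and was higher in 2 of 3 pairs.

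**Figure D4:**
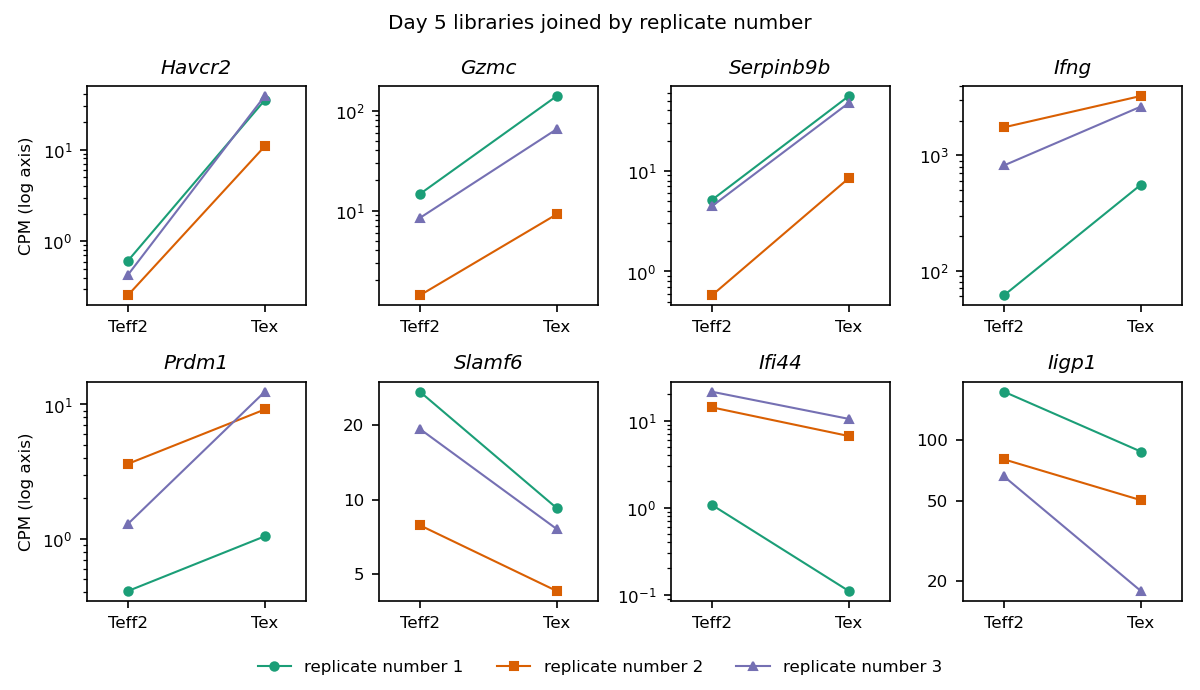
Transcript levels (CPM, log axes) of 8 genes in the 3 Teff2 and 3 Tex libraries, each line joining the libraries of 1 replicate number. The first 5 genes were higher in Tex and Slamf6, Ifi44 and Iigp1 lower in Tex in all 3 pairs, while the level of Ifng in Teff2 ranged from 61.1 to 1754 CPM between replicate numbers.

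Within pairs 221 of 13096 genes changed between Tex and Teff2, 126 higher and 95 lower, 57 and 22 of them by a log2 fold change of at least 1 (edgeR). Camera called 10 lists within pairs, 7 higher and 3 lower. Besides those above these were the stress response list (2 of 20 rose; camera adjusted p = 1.33e-07; adjusted p = 0.371 with an estimated correlation) and the IL-2 list (2 of 18 rose; camera adjusted p = 7.34e-07; adjusted p = 0.371 with an estimated correlation). They were also the respiratory list (0 of 28 called and 3 higher adjusted over the list alone; camera adjusted p = 7.00e-06; adjusted p = 0.371 with an estimated correlation), the amino acid list (0 of 18 called; camera adjusted p = 3.98e-03; adjusted p = 0.801 with an estimated correlation) and the G2 and M phase list (0 of 26 called; camera adjusted p = 8.32e-03; adjusted p = 0.820 with an estimated correlation), all higher. Without pair 1 the G2 and M phase list was not called and its direction was lower (camera adjusted p = 0.595). The chromatin-modifying enzymes were lower (0 of 28 called; camera adjusted p = 0.0227; adjusted p = 0.384 with an estimated correlation). With an estimated correlation 1 list had an unadjusted p under 0.05, and fry called none, with 5 at an unadjusted p under 0.05. Adjusted over the list alone, 4 stress response and 7 IL-2 genes rose. In the fit over 4 groups without pairs, 1 of 14332 genes was called and 251 had an unadjusted p under 0.05. DESeq2 called 5 genes. The groups did not overlap for 690 genes (4.81%). A level of 10% by chance holds for libraries that vary independently, which these pairs did not, so this share has no such level. In the fit over 4 groups camera called 7 lists, 5 higher and 2 lower. None of them was called with an estimated correlation (lowest adjusted p = 0.211 with an estimated correlation). Median, mean and test differed in sign for 4 uncalled lists in that fit (activation, exhaustion factors, receptors and adhesion molecules, p53 targets) and for 3 within pairs (exhaustion factors, receptors and adhesion molecules, chromatin architecture). Without pair 1, 2 or 3 the paired fit called 688, 529 and 39 genes, and without pair 3 it called 14 of the 35 named ones. The calls of Ifng, Prdm1, Csf2, Cd244, Entpd1, Eomes, Id2, Il2rb, Slamf6, Id3, Ifi44, Ifi203 and Gbp2 were among those that ended. With the spread of all 12 libraries it called 3 genes, Havcr2 and Gzmc among them. The call of Havcr2 without pairs ended in 9 of 16 alternatives.

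Teff2 and Tex were also compared with Tn directly. In Teff2, 7010 of 14332 genes changed, 3672 higher and 3338 lower, and in Tex 7584, 3909 higher and 3675 lower (edgeR). With upper-quartile factors more genes were lower than higher, 3270 higher and 3757 lower in Teff2 and 3481 and 4138 in Tex. Gzmb reached 6005 ± 3649 CPM in Teff2 and 8764 ± 3511 CPM in Tex from 14.9 ± 11.9 CPM in Tn, with log2 fold changes of 8.65 (SE 1.10) and 9.19 (SE 1.13). Ifng reached 878 ± 848 and 2165 ± 1427 CPM, with log2 fold changes of 7.21 (SE 1.38) and 8.51 (SE 1.46). Klf2 fell to 3.22 ± 1.08 and 3.17 ± 2.73 CPM, with log2 fold changes of -7.86 (SE 0.64) and -7.88 (SE 0.64). Tcf7, a transcription factor of naive and memory T cells, fell from 1322 ± 230 CPM to 223 ± 148 and 142 ± 95.4 CPM. All 26 G2 and M phase genes were higher than in Tn in both states, as were 28 and 29 of 29 S phase genes and 18 and 18 of 20 stress response genes. Of the 22 naive and memory genes 18 fell and 1 rose in each state, and of the 21 cytotoxic effector genes 12 rose and 5 fell in Teff2 and 14 rose and 4 fell in Tex. Adjusted over the list alone the cytotoxic counts were 14 and 6 in Teff2 and 14 and 4 in Tex. Those of the naive list were 1 and 18 in each state, those of the stress list 18 in each, those of the G2 and M phase list 26 in each and those of the S phase list 29 in each. The groups did not overlap for 8509 genes (59.4%) in Teff2 and 9077 (63.3%) in Tex, where chance gives 10%. Without Tn replicates 1 and 3, whose sums of B cell, MHC class II, NK and macrophage markers were higher, 3334 genes changed in Teff2 and 3944 in Tex. Of the calls, 1632 of the 3672 rises and 1584 of the 3338 falls of Teff2 and 1887 of the 3909 rises and 1920 of the 3675 falls of Tex remained called.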

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

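The alternatives with limma on the authors' log2 values, without Tn replicates 1 and 3 (with either correlation in camera), without replicate 1 of the activated states and with the replicate block on 6 libraries, and the whole fit within pairs, were chosen after the data were seen; the others were chosen beforehand. Where no cause is given below, the cause was not tested.

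Against Tn the counts of changed genes stayed within 1.5 times their size under every alternative but 1. Leaving out each library gave 5779 to 7228 genes for Teff1, 5842 to 7616 for Teff2 and 6502 to 8021 for Tex. Without Tn replicates 1 and 3 the counts were 3015, 3334 and 3944, in a fit with 1 Tn library. Of 96 genes named as called between Teff1 and Tn, 87 stayed called under the alternatives chosen beforehand and 68 under all, and none turned direction.

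For Teff2 and Teff1 the count of 96 genes became 499 with DESeq2, 39 with only the 6 libraries compared, 313 with the replicate block and 277 with the replicate block on 6 libraries. Leaving out a library gave 23 to 106 genes, with 25 without Teff2 replicate 3 and 41, 26 and 23 without Teff1 replicate 1, 2 or 3. Of 14 named genes 6 stayed called throughout.

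For Tex and Teff2 the count of 1 gene became 5 with DESeq2. It was 0 in edgeR with upper-quartile factors (247 genes at an unadjusted p under 0.05), with the stricter filter of 2 CPM (203), with only the 6 libraries compared (176) and without replicate 1 of the activated states (332). Leaving out a library gave 0 to 1 genes, 1 without Tex replicate 2 and 0 otherwise, with 228 to 461 genes at an unadjusted p under 0.05. The replicate block over all 12 libraries left 1 gene, and the replicate block on the 6 day 5 libraries gave the 221 of the paired fit, whose dispersion is estimated from these libraries alone. Within pairs the 221 genes became 335 with DESeq2, 968 with no low-count filter and 3 with the spread of all 12 libraries; without pair 1, 2 or 3 they became 688, 529 and 39. Of 35 named genes 14 stayed called without pair 3 and 2, Havcr2 and Gzmc, under all alternatives. The replicate block gave 8053, 7984 and 8548 genes for Teff1, Teff2 and Tex against Tn.

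Camera with an estimated correlation called 0 lists for Teff1 and Tn (4 at an unadjusted p under 0.05; fry called 16) and 0 without Tn replicates 1 and 3, where the preset correlation gave 17, 0 for Teff2 and Teff1 (2), 0 for Tex and Teff2 (3) and 0 within pairs (1). Fry called 0 lists for Teff2 and Teff1 (4 at an unadjusted p under 0.05), 0 for Tex and Teff2 (0) and 0 within pairs (5), where camera with the preset correlation called 11, 7 and 10. Leaving out each pair, that camera test called 10 to 12 lists.

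Without Tn replicates 1 and 3, 26, 18 and 24 of the genes called for Teff1, Teff2 and Tex against Tn turned direction, and 1 did for Teff2 against Tn without replicate 1 of the activated states. The G2 and M phase list for Teff2 and Teff1, called lower by camera, was called higher without replicate 1 of the activated states. Genes of the sorted proteins that were not called turned direction too. For Teff2 and Teff1 the log2 fold change of Havcr2 was -0.0839 to 0.595 when a library was left out. For Tex and Teff2, leaving out a library gave -0.123 to 0.0339 for Cd8a, -0.186 to 0.494 for Cd44 and -0.0569 to 0.445 for Pdcd1, and Cd44 was at -0.145 without replicate 1 of the activated states. Within pairs Cd44 ranged from -0.157 to 0.375.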

Other observations

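The tests of explanations in the paragraphs on spleen cells, replicate 1 and the changes within pairs were chosen after the results were seen; the counts of splits were planned, apart from the arrangements within pairs.

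Other splits of the same libraries into groups of 3 gave at most 0 genes, where the real split gave 7262 for Teff1 and Tn, 39 for Teff2 and Teff1, 6607 for Teff2 and Tn and 7460 for Tex and Tn, so in each 1 of 10 splits reached the real count. For Tex and Teff2 the real split and the highest other gave 0, so 10 of 10 did. Within pairs the real arrangement gave 221 genes and the highest other 0, so 1 of 4 did. These splits are too few for a share under 0.05.

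Markers of several other spleen cell types were higher in Tn than in the activated states. In the activated states the sums of dendritic cells and of CD4 and regulatory T cells were led by the activation genes Batf3 and Il2ra. Without these genes the dendritic cell sum was 38.8, 6.48 and 45.9 CPM in Tn replicates 1, 2 and 3. The CD4 and regulatory T cell sum was then 95.5, 26.9 and 114 CPM. For MHC class II markers a fall of these genes within CD8+ T cells was argued against. Their sum differed at least 14.1-fold between Tn libraries, while the CD8 T cell markers differed 1.4-fold. The NK cell sum differed at least as much, but Gzma, its most abundant member, is also in the cytotoxic list. An uneven share of CD8+ T cells with Gzma could add to this difference, so the test cannot decide for NK cell markers. The same test could not decide for B cell, macrophage, erythroid and stromal markers, whose sums differed 1.14-fold (stromal) to 3.87-fold (B cells). These lie under the limit for arguing against such a fall, which was chosen after the results were seen. An even share of other cells in the Tn libraries would give small differences too. The neutrophil, platelet and gamma delta T cell sums were lowest in Tn replicate 2, and the erythroid sum was lowest in Tn replicate 3. A candidate explanation for 4 of these sums is that other spleen cells were left in the Tn sort, which was for CD8+ CD44- cells. The sums of 4 of 4 cell types (B cells, MHC class II, NK cells, macrophages) were lowest in Tn replicate 2. These 4 were chosen after their sums were seen, so the count restates what prompted the explanation. Their most abundant genes, Ighm, Cd74, Gzma and Lyz2, averaged 749, 460, 67.2 and 57.6 CPM in Tn. The fallen members of the naive and memory list differed by a median of 1.36-fold between Tn libraries (at most 6.16-fold). For the list as a whole, this argued against a fall caused by other spleen cells as uneven as the MHC class II sum. An even share of other cells would give small differences in this list too, so it was not excluded.

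Replicate 1 stood apart from replicates 2 and 3 in the activated states. Lower depth of replicate 1 was argued against, since it had the lowest total in 1 of 3 groups, and so were fewer CD8+ T cells, since its CD8 T cell sum was 0.976 to 1.03 times that of the others. Replicate 1 nearer to the naive state may be part of it: 69.8% and 75.6% of the genes called between Teff1 and Tn deviated towards Tn in replicate 1 of Teff2 and Tex, but no label gives a culture, animal or batch, which keeps this open.

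For the changes of Tex against Teff2 within pairs, macrophages and monocytes in the TIM-3+ sort were argued against as a candidate cause, because the macrophage and monocyte sum was higher in Tex in 0 of 3 pairs, with a mean ratio of 0.784. Dendritic cells in the TIM-3+ sort may still contribute: without Batf3, an activation gene, their sum was higher in Tex in 2 of 3 pairs, with a mean ratio of 1.27. Most of the difference in the full sum came from Batf3. NK cells and gamma delta T cells in the TIM-3+ sort were not tested as a cause. A step further along the change from Tn to Teff1 was also examined. Of the 126 genes higher in Tex, 47.6% were higher in Teff1 than in Tn, against 51.4% of all genes. This is under the 60% taken as excluding such a step. It cannot decide, because markers of other spleen cells were uneven between the Tn libraries. Gzma, higher in Tex, fell from 67.2 ± 63.3 CPM in Tn to 0.653 ± 0.612 CPM in Teff1. Of the 95 genes lower in Tex, 70.5% were lower in Teff1 than in Tn, against 48.6% of all genes. That share lies between 75%, taken as what such a step needs, and 60%, taken as excluding it. Both limits were chosen after the results were seen. This share rests on the same uneven Tn libraries, so it cannot decide either.

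Other called genes within pairs were noticed after their values were seen, each in the same direction in 3 of 3 pairs (edgeR). Vim, a cytoskeletal protein, had 580 CPM in Teff2 and 986 CPM in Tex (log2 fold change 0.99, adjusted p = 0.0330), and S100a6, a calcium-binding protein, 7.27 and 16.6 CPM (1.17, adjusted p = 0.0149). The transcription factors Myb and Tcf7 had 133 and 65.0 CPM (-1.01, adjusted p = 0.0164) and 223 and 142 CPM (-0.67, adjusted p = 0.0204).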
